A study of Mus musculus with 13 samples.

How the data were processed

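High-throughput genome-wide translocation sequencing (HTGTS) recovers the sequences that joined to one fixed DNA break, called the bait. Here the bait was a cassette with recognition sites of the I-SceI nuclease, placed either in the immunoglobulin heavy chain locus (IgH) on mouse chromosome 12 or at c-myc on chromosome 15. The 13 libraries form 4 groups by locus and cell type, namely 3 libraries of IgH B cells, 3 of IgH T cells, 3 of c-myc B cells and 4 of c-myc fibroblasts. Per the labels' protocols, genomic DNA was sonicated, libraries were made by adapter PCR, and reads came from a MiSeq. B cells were activated with anti-CD40 and IL-4, T cells with ConcanavalinA and IL-2, and the fibroblasts were SV40-transformed tail cells without activation, per the labels. Nothing in the labels says that replicates came from separate animals or cultures.

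The deposited tables hold 1 line per read, with the prey position, strand, aligned part, read sequence and a gene label, per the file headers. The alignment score is deposited as the authors' aligner gave it, in matched bases less penalties as its values show. Reads were placed on mm9, per the submitters' processing notes, while the aligner, its version and the filters are not given in the sources used here. Prey reference sequences held an I-SceI site in some lines of every group but the fibroblasts, so the references used there also held cassette sequence. Positions are given as in those tables, counted from 1. No mm9 genome or gene annotation was at hand, so gene names are those in the deposited tables, and distances to transcription start sites were not analysed here.

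Lines were counted as deposited, because no line repeated all coordinates of another in its library, the start of the prey on the read included. Position, strand and far end alone were repeated in 21.6 percent of lines of c-myc B-cell replicate 14, against 0.718 to 4.69 percent in the other libraries and 6.11 percent over all. Such lines can be duplicates, and counting 1 of each was an added alternative. In replicate 14 they need not be, since 81.5% of its prey fragments on other chromosomes ended in GG. In the deposited tables, junctions repeated a position and strand on the cassette chromosome but not elsewhere. Among 2012 junctions off the cassette chromosome of their locus, 0 shared position and strand with another of the same library and 0 lay within 3 bp of one, although 21 lay within 5 bp. On chromosome 12 of the IgH libraries, 1518 of 6595 junctions repeated a position and strand, and on chromosome 15 of the c-myc libraries 2232 of 7848 did. Shares on other chromosomes may therefore be low relative to those on the cassette chromosome, and values with 1 junction per position and strand are given beside them. The step from 0 junctions within 3 bp to 21 within 5 bp argues against the density of junctions alone, for those off the cassette chromosome. How the lines were handled before deposit was not tested.

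Break windows were set before the data were examined as the 2 highest 5 kb windows of the cassette chromosome at least 20 kb apart, pooled over the libraries of a locus with equal weight, and widened to 10 kb on either side of the peak. At IgH the bait peak was at 114577038 and the partner peak at 114664493 of chromosome 12. At c-myc they were at 61818880 and 61923263 of chromosome 15. The c-myc B-cell libraries alone had their partner peak at 61914760, which is 8503 bp away, so that their window by this rule holds only part of the cluster on that side. Values with the window of each genotype were added after this was seen. All 3101 words of 24 bases shared by c-myc B cells and fibroblasts downstream of the B-cell peak lay 172 bp apart. The 8503 bp therefore mix coordinates of references that differ by this much there.

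The long-range, local and other-chromosome shares are junctions in the partner window, in the bait window and on other chromosomes as percent of a library. The same-chromosome share is the part of junctions outside both windows that lay on the cassette chromosome, and orientation is the percent of + strand junctions in the partner window. Groups were compared by two-sided exact permutation tests of the difference between group means, with Benjamini-Hochberg adjustment over 15 tests of shares and orientation, and over 6 tests of gene lists. With 3 against 3 libraries the smallest possible p is 0.1, and with 3 against 4 it is 0.0571, so that no single test could pass 0.05. Intervals of single libraries are Wilson intervals at 95 percent, limits for a count of 0 come from 3 counts, and both cover counting error only.

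Recurrent windows were 100 kb windows with an excess of junctions by a one-sided Poisson test at adjusted p under 0.05 in at least 2 libraries of a group, with 1 Mb around the breaks left out. Tested on simulated data, the step called 0 to 0.06 windows on average per group in 50 simulations with uniform positions and no clusters, which were run after the windows had been seen. With junctions of the cassette chromosome shifted by up to 2 Mb, which keeps their broad spread, it called 1.08 on average and up to 5 in c-myc B cells, 0.1 on average in IgH B cells and 0 to 0.02 in the other groups. It recovered 100 percent of planted clusters of 3 junctions per library in simulated c-myc B-cell libraries. Shares per chromosome were compared with limma 3.58.1 in R 4.3.3 on the log2 of percent plus 0.5, for chromosomes with a mean of 5 junctions per library. On simulated c-myc B-cell and fibroblast libraries with 18 chromosomes, the step recovered 100 percent of 4-fold changes and made 0.08 calls per simulation without change. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

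Genes and regions named are, by a rule set beforehand, the cassette and antigen receptor loci with any junction, recurrent windows, and genes of preset lists with a junction in at least 2 libraries of a group. The 4 lists were antigen receptor loci, known off-targets of activation-induced deaminase (AID) in B cells, T-cell genes and fibroblast genes. Membership followed the deposited gene label, since a margin around genes needs an annotation. Other genes named were chosen after their values were seen.

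Junction structure was read by matching each read to the bait consensus of its locus, as microhomology, blunt or inserted bases. In c-myc B-cell tables the prey began only after the last bait base, with 0, 1 and 0 overlapping reads in the 3 libraries, against 63.8 to 66.7 percent in fibroblasts. Microhomology and blunt joins were therefore not compared with that group. A first version of the classification took cassette sequence further along the repeated array for inserted bases in 15.1 to 29.4 percent of the insertions of c-myc libraries and 2.39 to 6.02 percent of those of IgH libraries. Reads whose last 8 bases before the prey were common bait sequence were then left unclassified. That change was made after the results had been seen. Reads with over 20 bases between bait end and prey were not classified either, so that longer insertions are left out. In all, 9.94 to 23.2 percent of junctions in IgH libraries were unclassified. In c-myc B cells it was 19.7 to 35.5 percent, and in fibroblasts 24.5 to 28.3 percent.

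IgH B and T cells share the replicate numbers 19, 21 and 23. Deviations from the group means over 21 bins of 1 kb correlated between samples of the same number at 0.558, 0.742 and 0.699, so the numbers were taken to pair the samples. Numbers 19 and 21 were on one sequencing run and 23 on another by their read names, so that the pairing and the run overlap. The other 2 comparisons share no run between groups. Alternatives were other window widths, denominators, counting units, score filters, scales, pseudocounts and count minimums, a replicate block, and leaving out each library, the last also with a fixed set of chromosomes.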

Results

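Junctions from a fixed I-SceI break were sequenced in mouse cells with cassettes at IgH or at c-myc, to compare how often the bait break joined a partner break elsewhere on the same chromosome in different cell types. The 13 libraries held 16455 junctions. Libraries of IgH B cells held 483 to 1115 junctions, those of IgH T cells 387 to 2707, those of c-myc B cells 878 to 2918 and those of c-myc fibroblasts 562 to 980.

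IgH B and T cells joined the bait break in S gamma 1 to the partner window, whose peak lay 87.5 kb away on chromosome 12. Which of them did so more often depended on how junctions were counted. The partner window also covers the switch region S mu, so that not every junction in it need be a join to the cassette. The partner break took 40.2% ± 3.12 (SD, n = 3) of junctions in B cells and 37.2% ± 1.58 (SD, n = 3) in T cells. The libraries of both groups overlapped (exact permutation p = 0.3, adjusted p = 0.3), while B cells were higher in all 3 pairs of replicate numbers, by 1.33 to 4.75 points (exact sign-flip permutation p = 0.25, the smallest possible). The difference of 3.01 percentage points changed to -0.596 with 1 junction per position and strand. With windows of 5 kb on either side it was 4.33 points with B cells higher throughout, and with junctions of the bait window left out of the denominator it was -16.7 points with T cells higher throughout (exact permutation p = 0.1 in each, the smallest possible). No direction can thus be given for this measure.

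**Figure D1:**
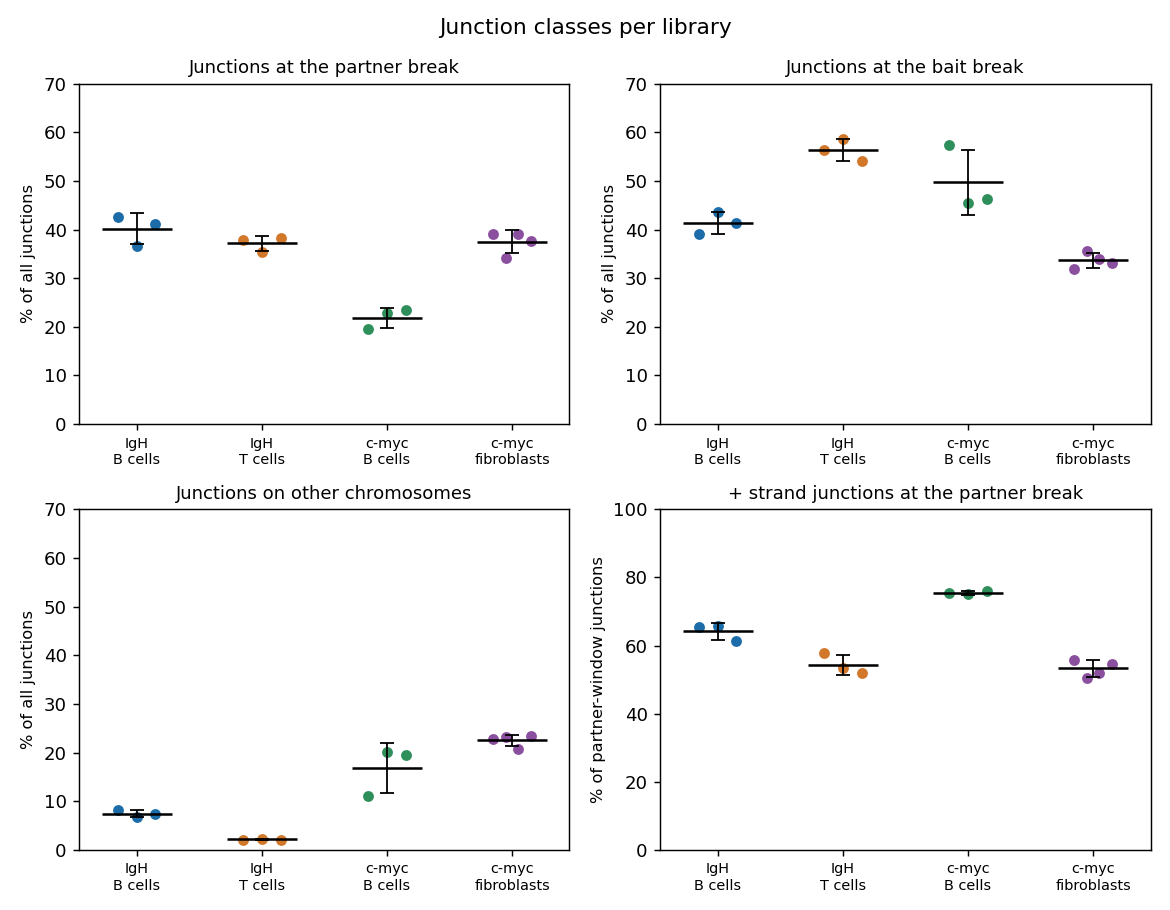
Percent of junctions per library at the partner break, at the bait break and on other chromosomes, and percent of + strand junctions at the partner break. Points are libraries, lines are group means and bars are the SD; c-myc B cells had 21.9% of junctions at the partner break on average and c-myc fibroblasts 37.5%.

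B cells had fewer junctions near the bait than T cells and more on other chromosomes. The bait window held 41.4% ± 2.23 (SD, n = 3) of junctions in B cells and 56.3% ± 2.28 (SD, n = 3) in T cells. Other chromosomes held 7.44% ± 0.710 (SD, n = 3) in B cells and 2.14% ± 0.127 (SD, n = 3) in T cells, a 3.47-fold difference. With 1 junction per position and strand these shares were 9.02% and 2.69%. Junctions at the partner break lay on the + strand in 64.2% ± 2.52 (SD, n = 3) in B cells and in 54.3% ± 2.97 (SD, n = 3) in T cells. No libraries overlapped in these 3 measures, and each had the smallest exact permutation p of this design, 0.1, with adjusted p = 0.115. More than 200 bp from the partner peak the libraries overlapped in orientation, at 10.2 points (exact permutation p = 0.2). The same-chromosome shares overlapped as well, at -6.93 points (exact permutation p = 0.3), and were -13.6 points apart with windows of 5 kb and 3.36 with windows of 20 kb on either side. Within the run of replicates 19 and 21, B cells minus T cells was -16.1 points for the bait window, 5.25 for other chromosomes and 10.2 for orientation. On the run of replicate 23 the differences were -12.6, 5.39 and 9.28 points.

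Switch regions, the repeated sequences that AID breaks during class switching, took junctions in B cells and rarely in T cells. S epsilon held 2.42% ± 1.23 (SD, n = 3) of junctions in IgH B cells and 0.0512% ± 0.0445 (SD, n = 3) in IgH T cells. S gamma 3 held 1.84% ± 1.49 (SD, n = 3) and 0.0266% ± 0.0461 (SD, n = 3), and 39 of its 55 B-cell junctions came from replicate 21. The tables also label a trans S mu, with 29 junctions in B cells and 0 of 4347 in T cells, which allows a share of up to 0.0690%. These lay inside the break windows, so the 1.16% of B-cell junctions they made up on average are part of the window shares above. S gamma 2b held 5 junctions in B cells and 2 in T cells, and S gamma 2a 1 and 0. Inside a stretch of S gamma 1 next to the bait break that appears to be absent from the cassette allele, B-cell libraries held 4, 12 and 4 junctions and T cells 0 of 4347. Apart from the trans label and, if it is absent there, this stretch, the tables do not tell on which copy of chromosome 12 a switch-region junction lies. Antigen receptor loci took 24.4% ± 7.51 (SD, n = 3) of junctions outside both windows in B cells and 2.28% ± 2.97 (SD, n = 3) in T cells (exact permutation p = 0.1, the smallest possible, adjusted p = 0.2). The break windows of the IgH libraries cover S mu and S gamma 1, so this share leaves both out and cannot be set beside that of c-myc B cells. T cells share the cassettes but were activated differently, and whether they give the background of this measure was not tested. T-cell replicate 23 had 0 of 30 junctions, which allows up to 10%.

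**Figure D2:**
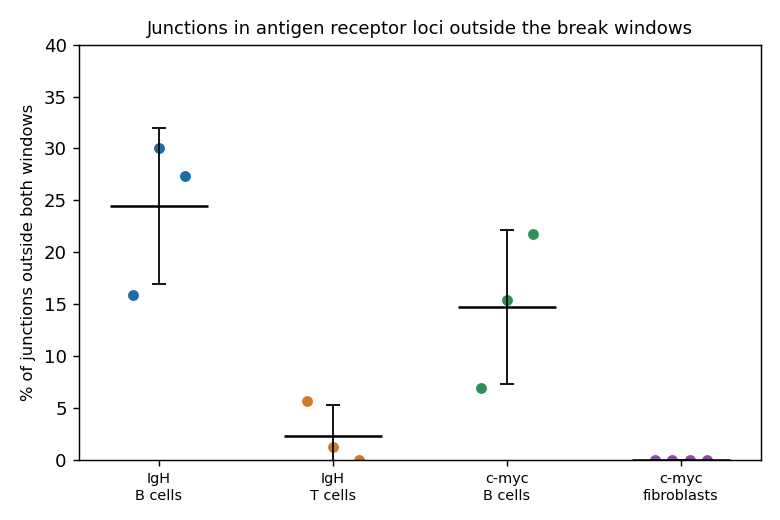
Percent of the junctions outside both break windows that the deposited labels place in antigen receptor loci. Points are libraries, lines are group means and bars are the SD; all 4 fibroblast libraries were at 0.

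At c-myc, B cells joined the partner break less often than fibroblasts. It took 21.9% ± 2.09 (SD, n = 3) of junctions in B cells and 37.5% ± 2.36 (SD, n = 4) in fibroblasts, and 23.3% ± 1.08 (SD, n = 3) in B cells with their own window. With 1 junction per position and strand the difference of -15.6 points was -4.14 points, with windows of 5 kb on either side, which leave out the B-cell cluster, it was -36.2, and 81.3% of fibroblast junctions in the partner window lay within 100 bp of its peak. The partner breaks were not the same site. The peak lay 95.9 kb from the bait in B cells and 104 kb from it in fibroblasts, whose genotype label lacks the partner cassette named for B cells. Each distance is in the coordinates of that group, which differ by 172 bp downstream of the B-cell peak.

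**Figure D3:**
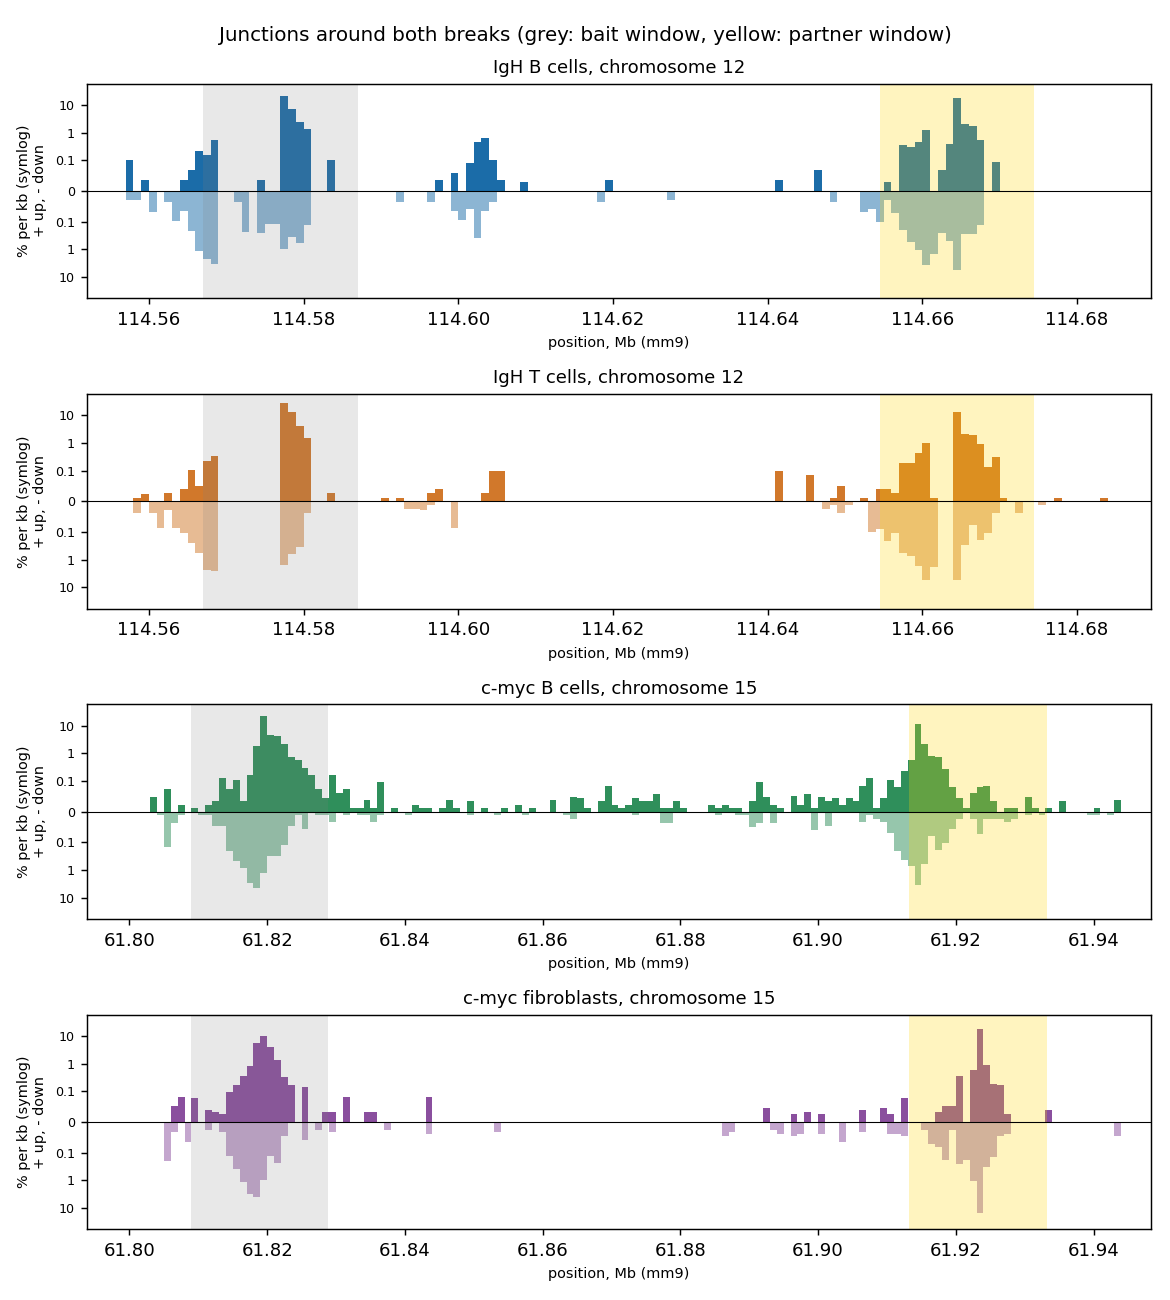
Mean percent of junctions per 1 kb along chromosomes 12 and 15, with + strand junctions up and - strand junctions down on a symmetric log axis that is linear below 0.1. The c-myc B cells peak near the left edge of the partner window and the fibroblasts 8503 bp further along.

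B cells had more junctions near c-myc itself and along chromosome 15. The bait window held 49.7% ± 6.68 (SD, n = 3) in B cells and 33.6% ± 1.51 (SD, n = 4) in fibroblasts, a difference of 16.1 points that was 8.60 points with 1 junction per position and strand. Of junctions outside both windows, 41.6% ± 9.38 (SD, n = 3) lay on chromosome 15 in B cells and 22.0% ± 1.69 (SD, n = 4) in fibroblasts. Part of the B-cell partner cluster counts as outside here, so that this difference of 19.65 points was 43.4 with windows of 5 kb and 16.4 with the window of each genotype. The stretch between both breaks held 2.46% ± 0.632 (SD, n = 3) and 0.851% ± 0.440 (SD, n = 4). Other chromosomes held 16.9% ± 5.11 (SD, n = 3) in B cells and 22.5% ± 1.16 (SD, n = 4) in fibroblasts, or 20.9% and 31.0% with 1 junction per position and strand. Without B-cell replicate 14, where 81.5% of fragments on other chromosomes ended in GG, that difference was -2.70 points, with every B-cell library still below every fibroblast library (exact permutation p = 0.133).

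Junctions at the partner break lay on the + strand in 75.5% ± 0.549 (SD, n = 3) in c-myc B cells and in 53.3% ± 2.50 (SD, n = 4) in fibroblasts. The difference of 22.3 points was 12.6 points with 1 junction per position and strand, and 7.60 points with windows of 5 kb on either side, where B-cell replicate 37 had only 3 junctions and was left out (exact permutation p = 0.133, the smallest possible with 2 against 4 libraries). More than 200 bp from the peak of each genotype it was 10.5 points and the libraries overlapped (exact permutation p = 0.343). The 5 share and orientation measures of B cells and fibroblasts each had the smallest exact permutation p of this design, 0.0571, with adjusted p = 0.115. The genotype labels, c-myc25-2xI and c-myc25xI with RosaI-SceI-GR, also differ in how I-SceI was supplied. Cell type, genotype, the supply of I-SceI and sequencing run changed together between these groups and cannot be told apart. The partner site and the rule that places the prey start changed with them. So did median read length, at 205 to 272 bases in B cells and 336 to 345 in fibroblasts. Identical junctions in several fibroblast libraries leave open whether those libraries are independent.

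Immunoglobulin switch regions on chromosome 12 were partners of the c-myc break in B cells. S gamma 1 held 106 junctions, S mu 103, S epsilon 30 and S alpha 3, while Jk2, Jk3 and the edge of C kappa on chromosome 6 held 1 each. S gamma 3, with 55 junctions in IgH B cells, held 0 of 6646 here, which allows up to 0.0451%. S gamma 2b and S gamma 2a held 0 as well. In replicates 14, 36 and 37, S gamma 1 held 9, 67 and 30 junctions, S mu 23, 58 and 22, and S epsilon 14, 11 and 5. Antigen receptor loci took 14.7% ± 7.44 (SD, n = 3) of junctions outside both windows in B cells and 0 of 849 in fibroblasts, which allows up to 0.353% (exact permutation p = 0.0571, the smallest possible, adjusted p = 0.171). Off-targets of AID held 18 of 1850 junctions in B cells and 0 of 849 in fibroblasts, with 6 in Ly6e, 4 in Cd83, a marker of activated B cells, and 3 in Pim1, which encodes a kinase. The exact permutation p was 0.0571, the smallest possible, with adjusted p = 0.171. In IgH B cells the same list held 2 of 474 junctions, both at Myc in replicate 21, and in IgH T cells 0 of 266 (exact permutation p = 1). Myc lies in the bait window of the c-myc libraries and cannot count there, and without it IgH B cells had 0 junctions of this list. The T-cell and fibroblast gene lists held 0 junctions in every group.

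Recurrent windows in c-myc B cells numbered 7, namely both IgH windows, those of Cd83 (4 of 5 junctions labelled so), Pim1 (3 of 5), Ly6e (6 of 10) and D15Ertd621e (3 of 5), and 1 on chromosome 15 from 60600001, where 1 of 8 junctions has a gene label. Fibroblasts had 0 recurrent windows. Of the 7 windows 3 lie on chromosome 15. There, simulated c-myc B-cell libraries with the broad spread of junctions along this chromosome but no clusters gave 1.06 windows on average, so that calls can arise without clusters. Of these 3, the Ly6e window passed the threshold in 3 libraries, while on other chromosomes those of Cd83 and Pim1 passed in 2. In IgH B cells and IgH T cells 1 window was recurrent, the same one on chromosome 6. Its 10 junctions all lay on the + strand within 35 bp, and the reads projected back to starts within 2 bp. This window held 2.14% of the other-chromosome junctions of IgH B cells and 6.25% of those of IgH T cells. It was not called in either group with adjustment over all windows, nor without replicate 19 or without replicate 21. The count in c-myc B cells was 3 without replicate 14, 3 without replicate 36, and 3 with adjustment over all windows.

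Inserted bases were found in 26.7% ± 4.19 (SD, n = 3) of classified junctions in c-myc B cells and 14.7% ± 1.02 (SD, n = 4) in fibroblasts (exact permutation p = 0.0571, the smallest possible). The tables of both groups place the prey start by different rules, so that this difference can come from processing. In IgH cells insertions made up 26.6% ± 6.01 (SD, n = 3) in B cells and 26.1% ± 3.97 (SD, n = 3) in T cells (exact permutation p = 1). Blunt joins made up 12.3% ± 1.42 (SD, n = 3) and 9.38% ± 0.404 (SD, n = 3) (exact permutation p = 0.1, the smallest possible), and microhomology 61.2% ± 4.62 (SD, n = 3) and 64.5% ± 4.37 (SD, n = 3) (exact permutation p = 0.5). Microhomology was lower in B cells in all 3 pairs of replicate numbers, by -5.17 to -2.06 points (exact sign-flip permutation p = 0.25, the smallest possible), but the difference between the groups was -5.805 to -1.17 points without single libraries. Outside both windows B and T cells had 61.6% ± 1.52 (SD, n = 3) and 72.3% ± 10.6 (SD, n = 3) microhomology and 13.96% ± 2.68 (SD, n = 3) and 8.07% ± 0.178 (SD, n = 3) blunt joins, without overlap in either (exact permutation p = 0.1, the smallest possible). The T-cell mean of microhomology rests on replicate 23, at 84% of 25 junctions, without which the difference of -10.7 points was -4.87.

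Between loci in B cells, IgH had more junctions at its partner break than c-myc and fewer on other chromosomes. The partner shares were 40.2% ± 3.12 (SD, n = 3) and 21.9% ± 2.09 (SD, n = 3), and those of other chromosomes 7.44% ± 0.710 (SD, n = 3) and 16.9% ± 5.11 (SD, n = 3). The bait windows held 41.4% ± 2.23 (SD, n = 3) and 49.7% ± 6.68 (SD, n = 3), the same-chromosome shares were 59.4% ± 5.67 (SD, n = 3) and 41.6% ± 9.38 (SD, n = 3), and + strand shares were 64.2% ± 2.52 (SD, n = 3) and 75.5% ± 0.549 (SD, n = 3). Each measure had the smallest exact permutation p of this design, 0.1, with adjusted p = 0.115. With windows of 5 kb on either side, which leave out the B-cell cluster at c-myc, the partner difference of 18.3 points was 36.9, the same-chromosome difference of 17.8 points was 4.67 with overlapping libraries (exact permutation p = 0.3), and the orientation difference of -11.3 points turned to 4.45 without c-myc replicate 37, which had too few junctions, and without overlap (exact permutation p = 0.2, the smallest possible with 3 against 2 libraries). The bait windows overlapped with windows of 20 kb, at -6.92 points (exact permutation p = 0.2). With 1 junction per position and strand the bait window difference was -4.80 points and that of orientation -6.84. Locus, cassette and sequencing run differ together here, and the IgH windows cover the switch regions S gamma 1 and S mu. Without c-myc replicate 14 the difference in the bait windows was -4.49 points, still without overlap (exact permutation p = 0.2, the smallest possible). Insertions did not differ beyond the spread between libraries, at -0.0889 points (exact permutation p = 1), and at -5.31 points with cassette sequence counted as inserted (exact permutation p = 0.3). Here too the tables of both groups place the prey start by different rules.

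Chromosome 13 held 0 of 179 junctions of IgH B cells outside chromosomes 12 and 15, which allows up to 1.68%, and 38 of 778 in c-myc B cells. This was at least 2.91-fold lower in IgH B cells over the groups, or 1.74-fold without IgH replicate 19 and 1.76-fold without IgH replicate 21. It was the 1 chromosome of 15 past the threshold by limma (adjusted p = 7.99e-05). Without c-myc B-cell replicate 36 chromosome 13 fell under the count minimum and was not among the 11 chromosomes tested, and with the same 15 chromosomes limma again called 1. The size of this p rests on IgH B-cell libraries that are all at 0. Between c-myc B cells and fibroblasts limma called 0 of 18 chromosomes, with 1 at an unadjusted p under 0.05. Too few junctions on other chromosomes kept IgH B and T cells from being compared at that minimum, and without a minimum limma called 0 of 18, with 0 at an unadjusted p under 0.05.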

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

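The tests in this part were chosen after the results they measure had been seen, except the test of a common origin inside the break windows, whose exclusion of cassette sequence was added afterwards.

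In c-myc B-cell replicate 14, 81.5% of prey fragments on other chromosomes ended in GG, against 0 to 15.1% in the other 12 libraries, although the label of this library states sonication. The reference sequence of the prey held an I-SceI site in 365 lines of c-myc B cells, 160 of IgH B cells, 87 of IgH T cells and 0 of fibroblasts. No fibroblast library passed Dixon's outlier bound in 9 measures, but with 4 libraries this test is weak, and the ratios of the other-chromosome share, 0.820, and of the share with a gene label, 0.813, came close.

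The partner peak of the fibroblasts lay at another position of chromosome 15 than that of c-myc B cells. The nearest match to the I-SceI site within 100 bp of it had 8 mismatches, which argues against cutting of a native I-SceI-like sequence. Words of 24 bases shared by both groups lay 172 bp apart, far less than the 8503 bp between the peaks. This argues against shifted coordinates as the source of that distance, although the coordinates do differ by 172 bp. A nuclease that cuts 3 bases from an NGG motif, as Cas9 does, may have made this break, since ends of both strands met within 1 bp at such a site, but 12.5% of nearby positions have that spacing and the labels name no such nuclease. A different allele in the fibroblasts was not tested.

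The + strand share at the partner break was lower in fibroblasts than in c-myc B cells. With the window of each genotype the difference was 20.5 points with no overlap, which argues against the pooled window as its source. Over 200 bp from the peak it was 10.5 points with overlapping libraries, so that a loss of - strand junctions close to the B-cell cassette may account for part of it. Both groups shared 0 sequencing runs, so a difference between runs cannot be told apart from cell type, genotype or the supply of I-SceI. Nor can it be told apart from the partner site, the rule for the prey start or read length. All of these stay open as untested.

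On other chromosomes 4 junctions with the same position, strand and bait end occurred in more than 1 fibroblast library, at Eefsec, Lzic, Ric8b and Maml3, against 0 in c-myc B cells, 0 in IgH T cells and 1 in IgH B cells, at Epb4.1l5. In 3 of the fibroblast junctions the far ends differed by over 3 bp, and in 1 they were the same. This cannot decide on carry-over of amplified molecules. Off the cassette chromosome each library holds only 1 line per position and strand, and the far end is that of the aligned part of the read. The 19 and 15 inserted bases at Ric8b and Eefsec held 0 common bait words, but 13 of those at Eefsec repeat the prey, and with 0 reads across either site they may lie in the fibroblast genome, so that independent joining stays open there as for the 2 junctions without inserted bases. Cells with a common origin remain another candidate explanation. The test set beforehand found 2 shared junctions with long insertions among 96 inside the windows, but the bases of both proved to be cassette sequence, which left 0 and decided nothing.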

How the results depend on the processing

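Alternatives with own windows, distinct far ends, adjustment over all windows, distances over 200 bp, cassette bases as insertions, a fixed set of chromosomes, structure outside both windows without single libraries, the AID list without Myc, and the block for structure and gene lists were chosen after seeing the data. Of 206 alternative values of shares and orientation, 202 kept their direction. No test of these could pass 0.05, so this says nothing about significance. Some of the 206 values could not change by construction. Other window widths leave the other-chromosome share as it is, and own windows leave that and the local share. The replicate block repeats the main difference. For IgH B minus T cells the long-range difference was -0.596 points with distinct positions and -16.7 with the bait window left out of the denominator, and the same-chromosome difference was 3.36 points with windows of 20 kb on either side. For IgH minus c-myc B cells, orientation was 4.45 points with windows of 5 kb and 2 c-myc libraries, which by construction leave out the B-cell cluster at c-myc. Insertions differed by -2.47 to 3.54 points between IgH B and T cells and by -3.04 to 2.97 between IgH and c-myc B cells when single libraries were left out, and by 1.17 in the latter outside both windows. Outside both windows without single libraries they ranged from -0.993 to 9.29 and from -0.875 to 3.59, with 0.566, 1.398 and 2.98 among the latter. The cause was not tested for the others.

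Recurrent windows numbered 0 in IgH B cells, 0 in IgH T cells and 3 in c-myc B cells with adjustment over all windows, and 1 in fibroblasts with windows of 200 kb. Without single libraries they ranged from 0 to 1, 0 to 1 and 3 to 7 in the first 3 groups. Chromosomes called between IgH and c-myc B cells ranged from 0 to 2 without single libraries. The 0 came without c-myc replicate 36, where chromosome 13 fell under the count minimum and was not tested, and the 2 without IgH replicate 21 with the set of chromosomes kept. Since the real count for c-myc B cells and fibroblasts was 0, all 35 of 35 splits gave as many by construction, with 0 as the highest other, so that the splits say nothing there. For IgH and c-myc B cells 10 splits are too few for a share under 0.05, where 1 split, the real one, gave 1 chromosome and the highest other was 0.

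With the replicate block, paired differences of IgH B minus T cells were 3.01, -15.0, -6.93, 5.30 and 9.88 points for the long-range, local, same-chromosome and other-chromosome shares and orientation. Their smallest exact permutation p is 0.25, so that no call could be made with the block or without it. The same holds for structure and gene lists, so the block says nothing about stability. Distinct positions gave the same chromosome counts as all lines, since other chromosomes hold no repeated positions, so that alternative tests nothing there. Gene lists with a margin of 10 kb were not run for lack of an mm9 annotation.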

Other observations

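Insertions were more frequent at the partner break than on other chromosomes in every library of the 4 groups. They made up 30.0% and 20.2% of classified junctions in IgH B cells, 28.3% and 17.2% in IgH T cells, 28.5% and 22.4% in c-myc B cells, and 14.9% and 11.6% in c-myc fibroblasts. The exact sign-flip permutation p within libraries was 0.25 in each group of 3 and 0.125 in fibroblasts, the smallest possible in each. On other chromosomes, IgH T replicate 23 had 1 insertion among 6 classified junctions and replicate 19 had 3 among 24. All lines were counted, and only those on the cassette chromosome repeat positions, so both places were not counted alike. Of junctions on other chromosomes, 60.1 to 74.9% carried a gene label in the 3 libraries of c-myc B cells and 43.4 to 59.5% in the 4 of fibroblasts. Without junctions in antigen receptor loci these shares overlapped, at 49.9 to 61.95% in B cells and 43.4 to 59.5% in fibroblasts (exact permutation p = 0.286), so that no difference beyond those loci was found.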
